A study of Mus musculus with 6 samples.

How the data were processed

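Total RNA of 6 samples of LβT2 cells, 3 with scrambled siRNA and 3 with Gas siRNA for 48 h, had been labelled with biotin and hybridised to Illumina MouseWG-6 v2.0 BeadChips, per the labels' protocols. The values used were the authors' processed intensity values, 1 per probe and array, on a linear scale. BeadStudio is named in the submitters' processing notes with no version, and the normalization method is not given in the sources used here. Sorted columns of the deposited intensity values agreed within 1.66% below the 10 brightest probes, as columns do after quantile normalization, and the lowest value was 97.6, so background had not been subtracted. The median intensity was 141 on every array. A second table of signals before normalization held 24 columns, of 6 arrays with 4 measures each, named by 1 chip number and a position. These 24 columns match no sample's labels and were not used here, so detection p-values and array positions were not used either.

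The design fixed before the data were examined had called for neqc on the signals before normalization and a filter on detection p-values. The columns of that table match no sample's labels, and matching them to samples by their values was not tried. The background of each array was therefore taken from the deposited values. Its mean came from the mode of the log2 intensity density (128 on each array) and its SD from the values below the mode (between 8.49 and 8.71). Normexp was run with these values and an offset of 16, followed by quantile normalization and log2. A probe was kept if it was above the 95th percentile of that background, an intensity between 143 and 144, on at least 3 of the 6 arrays. These parameters were set before the groups were compared. Where no array of a group lay above this bound, a fold is given as a lower limit: the mean log2 value of the bright group against, for each dim array, the higher of the lowest signal above the bound and the probe's own.

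Gene symbols came from the platform annotation, in which 34885 probes had 1 symbol and 18 had several, and 10378 probes were not listed. Symbols were compared through gene numbers with the RefSeq gene table of GRCm38.p6, which changed 0 of them. That table was also used for which genes neighbour each other, and no coordinates are given because the array files name no genome build. A gene was represented by its kept probe with the highest mean over all arrays, and 4382 genes had more than 1 kept probe.

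Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment over the 21535 kept probes and a threshold of 0.05. All adjusted p-values of genes come from this fit. Log2 changes are Gas siRNA minus scrambled siRNA. The prior had 24.2 degrees of freedom beside 4 residual ones, with a prior SD between 0.076 and 0.32 along intensity. Without the trend the prior had 3.62 degrees of freedom and a single SD of 0.16. The median SD within groups was 0.28 log2 in the dimmest 25% of genes and 0.093 in the brightest 25%. Gene lists were tested with camera at a correlation of 0.01 over representative probes, adjusted over the 25 lists with at least 5 kept members, and also with an estimated correlation and with fry, whose directional test asks whether a list moves on balance and whose mixed test asks whether members change either way. Fry compares a list with no other genes.

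Genes were named by a rule fixed before the data were examined: Gnas, the 12 largest rises and 12 largest falls among changed genes with non-overlapping groups, clone and predicted names left out, the genes of the study's question, and up to 4 changed members of each list, or 2 where none changed. The values of members of lists where none changed are not all given below. The design gives no pairing, and the replicate numbers were checked for it. The correlations of deviations from the group means between arrays of the same number were 0.017, 0.060 and 0.096. Between arrays of different numbers in the 2 groups they ranged from -0.081 to 0.023. A weak pairing is thus possible, but as the design gives none, the numbers were not taken as pairs in the main fit.

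The procedure was tested on simulated arrays, fitted over 21768 probes, with 200 genes changed between Gas siRNA and scrambled siRNA. They had the real means and, as noise, the SDs already moderated by eBayes with the intensity trend. The trend thus held in the simulation, which cannot test the choice of fitting it. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 56.1%, 78.1% and 90% of the genes, 11 of 163 calls were false, and 0 calls were made when no gene changed. Among the 25 lists, filled with independent noise of the same SD for every gene, the 1 list with all members shifted by 0.2 was found and 0 others were called. This does not cover correlated genes. Nor does it cover smaller shifts, such as the medians of 0.039 and 0.038 of the oxidative phosphorylation and ribosomal lists below. The alternatives tried were no background correction, the authors' processed values, normexp without controls and with an offset of 50, median scaling, cyclic loess, no filter, a filter at the 99th percentile on all 6 arrays, the replicate number as a block, no intensity trend, robust eBayes, array weights, each array left out, a 1.5-fold minimum, an adjusted p threshold of 0.1, probes averaged per gene, and the other list tests. A slide block does not apply, because the table before normalization names 1 chip number for its 6 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.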

Results

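Gene expression was measured in LβT2 cells, a mouse line derived from pituitary gonadotropes, the cells that make luteinizing hormone and follicle-stimulating hormone. The cells carried either a scrambled control siRNA or an siRNA labelled Gas for 48 h, with 3 samples in each group, and total RNA of each sample was hybridised to an Illumina mouse whole-genome BeadChip. Each array held values for 45281 probes. Between 46.3% and 47.1% of the probes lay above the background bound of their array, and 21535 probes were kept, of which 17900 had a single gene symbol and represented 11442 genes. Correlations between arrays of the same group across probes were 0.991 for every pair, and those between groups ranged from 0.989 to 0.991. The number of arrays, 3 per group, limits the precision of all values. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

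The target of the siRNA was examined first. Gas was read as Gs alpha, the stimulatory G protein subunit that couples receptors to adenylyl cyclase, encoded by Gnas. The brightest Gnas probe (ILMN_2632206) fell by 2.91 on the log2 scale (SE 0.0868, limma adjusted p = 6.08e-20), a level 7.51-fold lower with Gas siRNA. Its normalized log2 intensity was 11.81 ± 0.057 (SD, n = 3) with scrambled siRNA and 8.90 ± 0.062 (SD, n = 3) with Gas siRNA. A second probe (ILMN_1223437) fell by 3.01 (SE 0.119, adjusted p = 6.11e-17), or 8.04-fold. The other 5 kept Gnas probes lay near background and did not pass. Of these, 4 had log2 differences from -0.62 to 0.20 and 1 was above the background bound on 0 of the 3 Gas siRNA arrays, so its difference is not given, and 3 more probes were not kept. With all kept Gnas probes averaged, an alternative added after the data were seen, the log2 change was -1.12 (adjusted p = 4.11e-04, the highest of the alternatives, against 2.72e-22 for the lowest without 1 array).

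**Figure D1:**
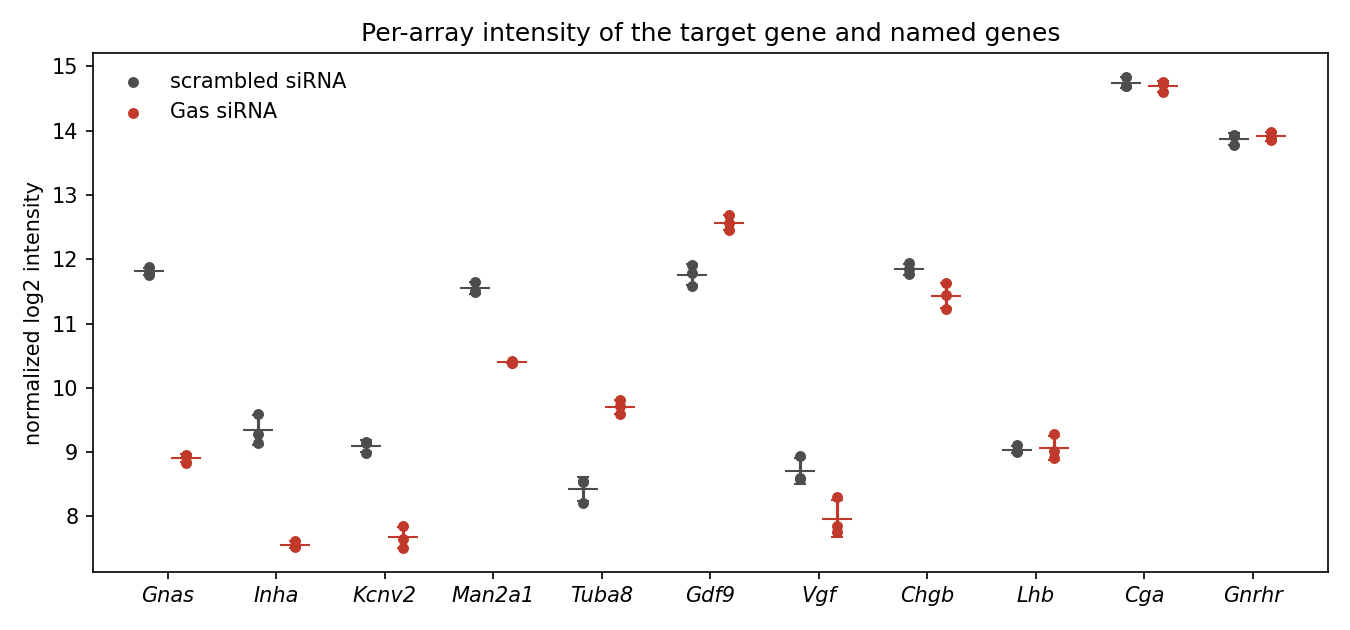
Normalized log2 intensity (vertical axis) of 11 genes (horizontal axis) on each of the 6 arrays, with scrambled siRNA in grey and Gas siRNA in red; points are arrays, horizontal marks are group means and bars are 1 SD. Gnas lay at 11.81 with scrambled siRNA and 8.90 with Gas siRNA, while the 2 groups overlapped for Lhb, Cga and Gnrhr.

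Gas siRNA was then compared with scrambled siRNA across all genes, which asks what else differed in cells with less Gnas transcript. Inha, which encodes the inhibin alpha subunit, fell 3.43-fold, a log2 change of -1.78 (SE 0.125, adjusted p = 1.14e-10). The modulatory potassium channel subunit gene Kcnv2, the melatonin receptor gene Mtnr1a and Man2a1, an enzyme of N-glycan processing in the Golgi, fell 2.69-fold, 2.44-fold and 2.23-fold. The alpha-tubulin gene Tuba8 rose 2.42-fold (log2 change 1.27, SE 0.112, adjusted p = 1.64e-08), and its second kept probe rose by 0.94 (adjusted p = 3.91e-06). In all, 196 genes changed at an adjusted p under 0.05, of which 84 were higher and 112 lower with Gas siRNA. Per probe, 261 passed, 114 higher and 147 lower, and 22 of them had no single gene symbol. Most changes were small: the median absolute log2 change of the changed genes was 0.53 (1.45-fold), 78 genes changed at least 1.5-fold and 15 at least 2-fold as measured, 2 of these, Tmem45b and Stac2, with 1 group below the background bound and lower limits of 1.61-fold and 1.68-fold. The arrays of the 2 groups did not overlap for 194 of the 196 changed genes, which their selection by adjusted p on the same arrays largely implies. They did not overlap for 16.1% of all genes, where chance gives 10% for 3 against 3. The count rested on modelling the variance along intensity: without the intensity trend 5 genes passed, namely Gnas, Inha, Kcnv2, Man2a1 and Tuba8, and every other gene named below lost its call. It fell to 104 without scrambled siRNA replicate 3, to 119 without Gas siRNA replicate 2 and to 114 without Gas siRNA replicate 3, and was 119 when the probes of a gene were averaged. Without scrambled siRNA replicate 2 the count of higher genes was 52.

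**Figure D2:**
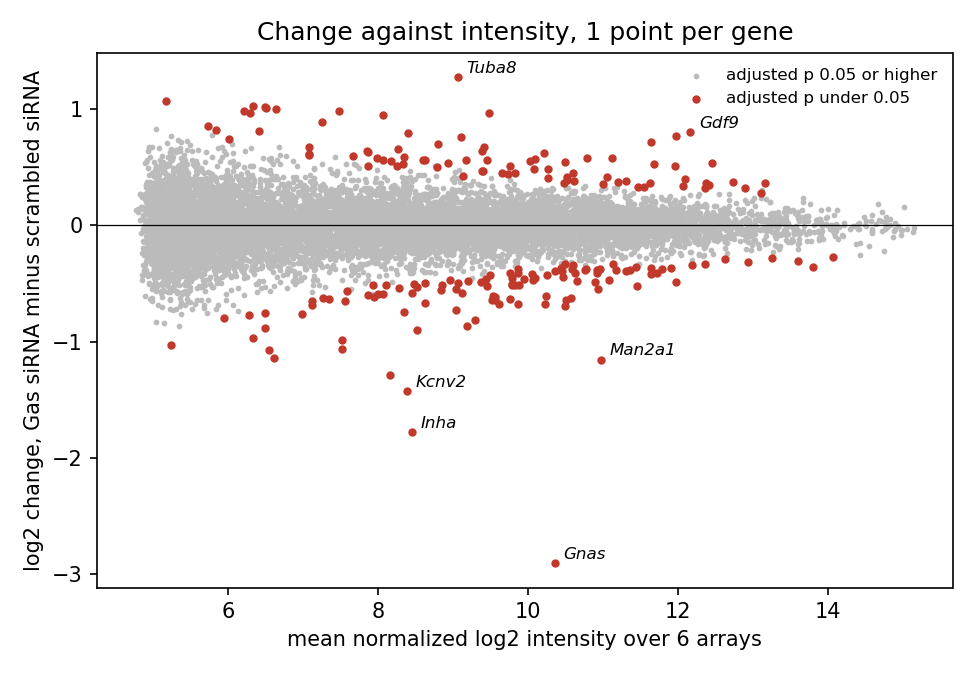
Log2 change with Gas siRNA against scrambled siRNA (vertical axis) by mean normalized log2 intensity over the 6 arrays (horizontal axis), 1 point per gene; red points are the 196 genes with an adjusted p under 0.05. Gnas at -2.91 and Inha at -1.78 lay farthest below 0 and Tuba8 at 1.27 farthest above.

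The 12 largest rises by the naming rule were, besides Tuba8 and 4 genes given separately below (Tmem45b, Agmat, Chp2 and Speer4d), those of Cpne9 (copine family), Mat1a (methionine adenosyltransferase), Cox6a2 (a muscle isoform of a cytochrome c oxidase subunit), Tcf7l1 (a transcription factor of the Wnt pathway), Omp (olfactory marker protein), Socs2 (a suppressor of cytokine signalling) and Snai3 (Snail family). The log2 changes of Cpne9, Cox6a2, Tcf7l1, Omp, Socs2 and Snai3 were 1.03, 0.99, 0.98, 0.97, 0.95 and 0.89, with adjusted p from 1.59e-06 for Omp to 0.00451 for Tcf7l1, and Mat1a had an adjusted p of 0.00204. The second kept Omp probe did not pass (0.32, adjusted p = 0.725). Agmat, Chp2 and Speer4d rose by 1.02, 1.01 and 0.97, and Tmem45b was at least 1.61-fold higher (adjusted p = 0.0140), its signal being below the background bound on all scrambled siRNA arrays. The calls of these 4 genes were lost when single arrays were left out. Agmat did not pass without scrambled siRNA replicate 2 (0.0835) or Gas siRNA replicate 3 (0.0823), and Chp2 without scrambled siRNA replicate 2 (0.0545), scrambled siRNA replicate 3 (0.0650) or Gas siRNA replicate 2 (0.0752). Speer4d did not pass without scrambled siRNA replicate 2 (0.0675), scrambled siRNA replicate 3 (0.0712) or Gas siRNA replicate 1 (0.0868), and Tmem45b without scrambled siRNA replicate 3 (0.0744), Gas siRNA replicate 1 (0.122) or Gas siRNA replicate 2 (0.0681).

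The 12 largest falls were, besides Inha, Kcnv2, Mtnr1a, Man2a1 and Stac2, which is given below as a lower limit, those of Rtp2 (a receptor transport protein), Tecta (alpha-tectorin), Cpa1 (carboxypeptidase A1), Ncan (the proteoglycan neurocan), Pde4d (a cAMP phosphodiesterase), Fcho2 (an endocytosis protein) and Pld1 (phospholipase D1). Their log2 changes were -1.14, -1.07, -1.07, -0.98, -0.97, -0.90 and -0.89. Stac2 was at least 1.68-fold lower (adjusted p = 0.0162), with no Gas siRNA array above the background bound. For Pde4d the other 2 kept probes did not pass (-0.12 and 0.034), and Pde4d did not pass with probes averaged (0.464). Pld1 did not pass without scrambled siRNA replicate 3 (0.0948). Stac2 did not pass without scrambled siRNA replicate 1 (0.0958), scrambled siRNA replicate 3 (0.0558), Gas siRNA replicate 1 (0.0945) or with no filter on dim probes (0.0670).

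The series concerns growth differentiation factor 9 and the expression of Fshb through activin receptor-like kinases, so the genes of that question were read individually. Gdf9 rose 1.75-fold with Gas siRNA, from 11.76 ± 0.16 to 12.57 ± 0.12 (SD, n = 3 each) in normalized log2 intensity (log2 change 0.80, SE 0.0832, adjusted p = 4.92e-07), on its 1 kept probe (ILMN_1225090). Vgf, a neuroendocrine secretory peptide precursor, fell by 0.74 (SE 0.139, adjusted p = 0.00303), and Chgb, chromogranin B, fell by 0.42 (SE 0.0875, adjusted p = 0.00974). The second kept probe of Vgf did not pass (-0.23), nor did Vgf with probes averaged (0.206). Chgb did not pass without scrambled siRNA replicate 1 (0.0587) or Gas siRNA replicate 3 (0.0985). The differences of Chga (-0.26, adjusted p = 0.0956), Scg2 (-0.16, 0.438) and the type I receptor gene Tgfbr1 (-0.30, 0.109) did not pass in this fit, and neither of the other 2 kept Tgfbr1 probes did (0.065 and 0.17). The gonadotropin subunit genes Lhb (0.027, SE 0.111) and Cga (-0.050, SE 0.0649), the GnRH receptor gene Gnrhr (0.042, SE 0.0669), Egr1 (0.070, SE 0.144) and Acvr1b (0.045, SE 0.188) did not pass either. The Fshb probe was above the background bound on 0 of the 6 arrays, so no Fshb level could be compared.

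Gene lists fixed before the data were examined were tested as groups with camera in limma at a preset correlation of 0.01, and 10 of 25 tested lists passed. With an estimated correlation 0 passed, so each camera call depends on presetting the correlation. For the CREB target (0.0092), cholesterol synthesis (0.0026) and imprinted (-0.020) lists the estimate was below the preset 0.01. A higher correlation thus cannot account for the loss of those calls. The list of ATF4 and amino acid response genes, which includes amino acid synthesis enzymes and stress-induced genes, was higher with Gas siRNA (adjusted p = 2.11e-10; adjusted p = 0.176 with an estimated correlation). Of its 30 measured members 27 had a positive log2 change, 4 rose, 0 fell and 26 did not pass over all genes tested, and 11 rose and 1 fell adjusted over the list alone. Nupr1, a stress-induced nuclear protein, rose by 0.77 (adjusted p = 1.09e-06), Chac1, a glutathione-degrading enzyme, by 0.58 (2.89e-04), Trib3, a pseudokinase, by 0.37 (0.0226) and Asns, asparagine synthetase, by 0.35 (0.0163). Of the other 2 kept Trib3 probes 1 rose by 0.54 and 1 did not pass (0.24, adjusted p = 0.522), and neither of the other 2 kept Asns probes passed (0.67 and 0.27). Trib3 did not pass without scrambled siRNA replicate 1 (0.0810), scrambled siRNA replicate 2 (0.0953), Gas siRNA replicate 3 (0.199) or with probes averaged (0.0578), and Asns without scrambled siRNA replicate 3 (0.147), Gas siRNA replicate 2 (0.117) or Gas siRNA replicate 3 (0.0961). The list call was kept without each array in turn. Of the 10 called lists it was the 1 that also passed directional fry (adjusted p = 0.0421), which compares a list with no other genes.

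**Figure D3:**
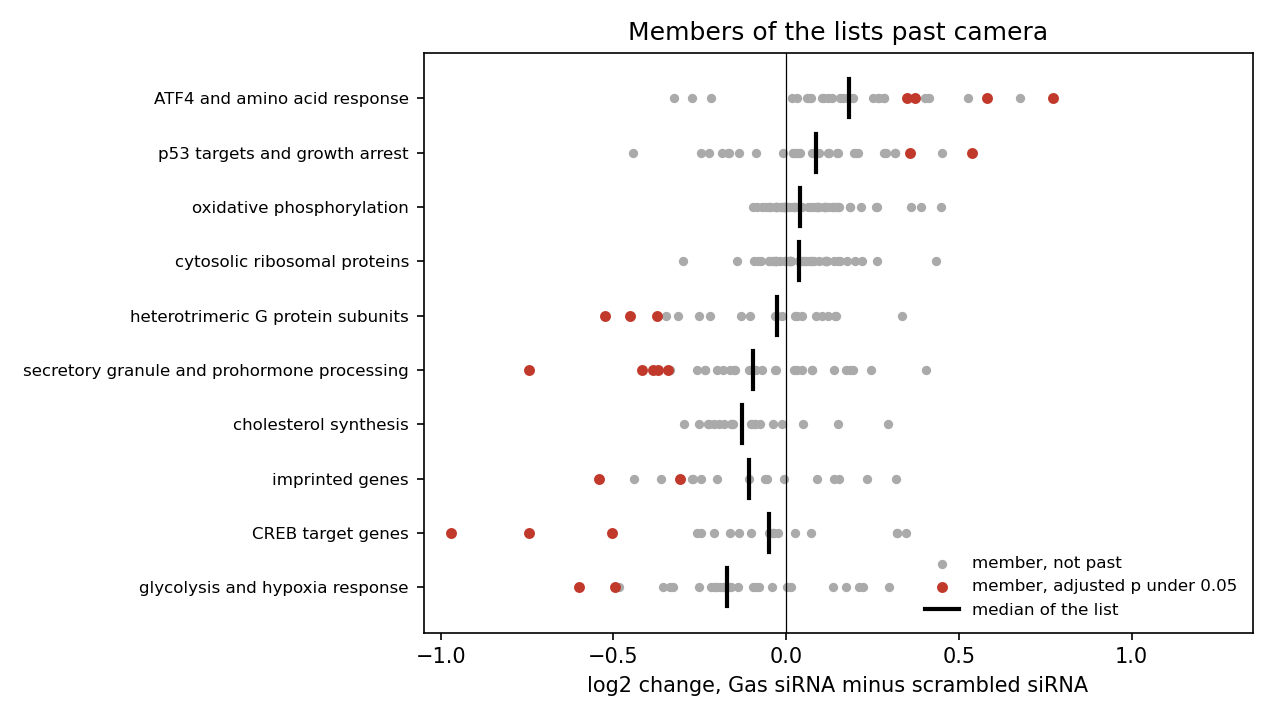
Log2 change with Gas siRNA against scrambled siRNA (horizontal axis) of the members of each list past camera (vertical axis); points are genes, red points passed an adjusted p under 0.05 and black bars are list medians. The ATF4 list has the highest median, 0.18, and the glycolysis and hypoxia list the lowest, -0.17.

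The secretory granule and prohormone processing list was lower with Gas siRNA (adjusted p = 0.00174; adjusted p = 0.206 with an estimated correlation). Of 30 measured members 5 fell, 0 rose and 25 did not pass, and adjusted over the list alone 8 fell and 1 rose. Besides Vgf and Chgb, the granule protein gene Scg3 fell by 0.39 (adjusted p = 0.0114), the granule transport GTPase gene Rab27a fell by 0.37 (0.0140) and the synaptotagmin gene Syt4, named here after its value was seen, fell by 0.34 (0.0163). Scg3 did not pass without scrambled siRNA replicate 2 (0.0643), scrambled siRNA replicate 3 (0.0678) or Gas siRNA replicate 1 (0.0711), Rab27a without scrambled siRNA replicate 2 (0.0892), Gas siRNA replicate 2 (0.0752) or Gas siRNA replicate 3 (0.107), and Syt4 without scrambled siRNA replicate 3 (0.0787) or Gas siRNA replicate 1 (0.151). Chgb lost its call without scrambled siRNA replicate 1 and Gas siRNA replicate 3, as above.

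CREB target genes, induced through cAMP and protein kinase A, were lower as a list (adjusted p = 0.0119; adjusted p = 0.206 with an estimated correlation). Of 19 measured members 3 fell (Pde4d, Vgf and Per2) and 16 did not pass, and 4 fell adjusted over the list alone. Pde4d and Vgf did not pass with probes averaged, as above. The clock gene Per2 fell by 0.51 (adjusted p = 0.0191). Its other kept probe did not pass (-0.20), and its call was lost without scrambled siRNA replicate 1 (0.0767), scrambled siRNA replicate 3 (0.101), Gas siRNA replicate 1 (0.0818), Gas siRNA replicate 2 (0.0819) or with probes averaged (0.122). The list did not pass with no filter on dim probes (0.0882). The cAMP and protein kinase A pathway list itself did not pass (adjusted p = 0.804). Pde4d was the 1 of its 32 members that fell, also adjusted over the list alone, though not on its other kept probes.

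Glycolysis and hypoxia response genes were lower as a list (adjusted p = 5.87e-06; adjusted p = 0.301 with an estimated correlation, estimated at 0.225 for this list). Of 28 members 2 fell and 26 did not pass over all genes, and 8 fell adjusted over the list alone. The prolyl hydroxylase subunit gene P4ha2 fell by 0.60 (adjusted p = 0.0198) and the stress-responsive gene Ndrg1 fell by 0.50 (0.0456). Their other kept probes did not pass (-0.66, adjusted p = 0.0503, for P4ha2 and -0.076 for Ndrg1). P4ha2 did not pass without scrambled siRNA replicate 1 (0.107), scrambled siRNA replicate 3 (0.0556), Gas siRNA replicate 2 (0.0848) or Gas siRNA replicate 3 (0.137). Ndrg1 did not pass without any 1 array other than scrambled siRNA replicate 2 (adjusted p from 0.0679 to 0.293, the highest without scrambled siRNA replicate 3), with the other normexp (0.0510), with no filter on dim probes (0.0697), with the stricter filter (0.0506) or with probes averaged (0.381). Cholesterol synthesis genes were lower as a list (adjusted p = 0.0166; adjusted p = 0.206 with an estimated correlation) with a median log2 change of -0.13, though 0 of 20 members changed singly in the fit of all 6 arrays and 1 fell adjusted over the list alone. Sqle, squalene epoxidase, had the smallest p of the list (-0.30, adjusted p = 0.0703), and it passed without scrambled siRNA replicate 2 (-0.37, 0.0362). The cholesterol list did not pass without scrambled siRNA replicate 1 (0.0557) or Gas siRNA replicate 1 (0.0757).

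Oxidative phosphorylation genes were higher as a list by a median of 0.039 (adjusted p = 0.0128; adjusted p = 0.275 with an estimated correlation), and cytosolic ribosomal protein genes by a median of 0.038 (adjusted p = 0.0445; adjusted p = 0.368 with an estimated correlation). None of the 57 and 50 measured members changed singly in the limma fit of all 6 arrays without a block, where the smallest adjusted p belonged to Ndufb2 (0.45, adjusted p = 0.163) and Rpl13a (0.26, adjusted p = 0.159), and 0 passed adjusted over the list alone in either. The oxidative phosphorylation call was lost without scrambled siRNA replicate 3 (0.0697) or Gas siRNA replicate 3 (0.0602). The ribosomal call was lost without scrambled siRNA replicate 2 (0.0630), scrambled siRNA replicate 3 (0.359), Gas siRNA replicate 1 (0.119), Gas siRNA replicate 2 (0.0530), with median scaling (0.0602), with no filter on dim probes (0.0899) or without the intensity trend (0.155).

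Heterotrimeric G protein subunit genes other than Gnas were lower as a list (adjusted p = 0.0445; adjusted p = 0.348 with an estimated correlation), with 3 of 22 members falling and 19 not passing, and 3 falling adjusted over the list alone. Gng2 fell by 0.53 (adjusted p = 3.56e-04) and its second kept probe fell by 0.67, Gng4 fell by 0.45 (0.0196), and Gnaq, the Gq alpha subunit gene, fell by 0.37 (0.0156). Gng4 did not pass without scrambled siRNA replicate 1 (0.0867), scrambled siRNA replicate 2 (0.125) or Gas siRNA replicate 3 (0.143). The other 2 kept Gnaq probes did not pass (-0.25 and -0.13), and Gnaq did not pass without any 1 array other than scrambled siRNA replicate 2 (adjusted p from 0.0543 to 0.0768, the highest without Gas siRNA replicate 3) or with probes averaged (0.309). The list did not pass without scrambled siRNA replicate 1 (0.0656), scrambled siRNA replicate 2 (0.169), Gas siRNA replicate 2 (0.0530), Gas siRNA replicate 3 (0.190), with no filter on dim probes (0.0899), without the intensity trend (0.162), with array weights (0.0566) or with probes averaged (0.192).

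Genes of p53 targets and growth arrest were higher as a list (adjusted p = 0.0445; adjusted p = 0.348 with an estimated correlation), with 2 of 30 members rising and 28 not passing, and 3 rising adjusted over the list alone. These 2 were the DNA damage-inducible gene Gadd45a (0.54, adjusted p = 0.0197, with 0.51 on its second kept probe) and the cyclin-dependent kinase inhibitor gene Cdkn2b (0.36, 0.0292). Gadd45a did not pass without scrambled siRNA replicate 1 (0.135), scrambled siRNA replicate 2 (0.0502) or Gas siRNA replicate 3 (0.168), and Cdkn2b without any 1 array other than scrambled siRNA replicate 1 (adjusted p from 0.0624 to 0.164, the highest without scrambled siRNA replicate 2), with no filter on dim probes (0.0528) or with probes averaged (0.0519). The p53 list did not pass without scrambled siRNA replicate 1 (0.163), scrambled siRNA replicate 2 (0.0936), Gas siRNA replicate 3 (0.497), with no filter on dim probes (0.237), with the stricter filter (0.0558), without the intensity trend (0.111) or with array weights (0.0566).

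Imprinted genes were lower as a list (adjusted p = 0.0210; adjusted p = 0.206 with an estimated correlation). Of 17 members 2 fell and 15 did not pass, and 4 fell adjusted over the list alone. Nnat (neuronatin) fell by 0.31 (adjusted p = 0.0253) and Mest fell by 0.54 (0.0490). Of their other kept probes 1 fell for each gene, with changes of -0.49 and -0.72, and 1 did not pass (-0.20 and -0.47). Nnat did not pass without scrambled siRNA replicate 2 (0.0955), scrambled siRNA replicate 3 (0.161), Gas siRNA replicate 3 (0.185) or with no filter on dim probes (0.0766), and Mest without any 1 array other than Gas siRNA replicate 3 (adjusted p from 0.0558 to 0.282, the highest without Gas siRNA replicate 1), with no background correction (0.0544), with the authors' processed values (0.0544), with the other normexp (0.0547), with no filter on dim probes (0.0765), with the stricter filter (0.0548) or with probes averaged (0.120). The list did not pass without Gas siRNA replicate 1 (0.0938) or without the intensity trend (0.0722).

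The other 15 tested lists did not pass. Among gonadotrope identity and hormone genes 1 of 21 rose (Gdf9) and 1 fell (Inha), and adjusted over the list alone 2 rose and 1 fell (list adjusted p = 0.486). Inha and Gdf9 were also the 2 changed members of the 33 TGF-beta, activin and BMP signalling genes (list adjusted p = 0.301), where 2 rose and 2 fell adjusted over the list alone. Among 15 G protein-coupled receptors of pituitary cells Mtnr1a fell by 1.29 and the dopamine receptor gene Drd4 fell by 0.61 (adjusted p = 5.35e-04; list adjusted p = 0.601), and 1 rose and 2 fell adjusted over the list alone. Of 30 unfolded protein response genes 4 rose, Sel1l by 0.53 (adjusted p = 1.28e-04), Wfs1 by 0.76 (0.00264), Chac1 and Trib3, the last 2 also in the ATF4 list, and 6 rose and 1 fell adjusted over the list alone (list adjusted p = 0.117). Sel1l had 3 other kept probes that did not pass (-0.069, 0.33 and 0.30), and it did not pass with probes averaged (0.316). Trib3 lost its call without scrambled siRNA replicate 1, scrambled siRNA replicate 2 and Gas siRNA replicate 3, as above.

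Of 26 genes in the list of immediate early and GnRH-induced genes Tsc22d1 fell by 0.64 (adjusted p = 4.08e-05, list adjusted p = 0.590). It did not pass with probes averaged (0.0534) or on its other kept probe (-0.19). Of 15 Wnt and beta-catenin targets Tcf7l1 rose (list adjusted p = 0.336). Adjusted over the list alone 1 gene passed in each of these. Among 38 calcium, PKC and Gq genes Gnaq and Prkcb fell, also adjusted over the list alone (list adjusted p = 0.0758), and Prkcb, a protein kinase C gene, fell by 0.29 (0.0463). The other 2 kept Prkcb probes did not pass (-0.099 and -0.15), and Prkcb did not pass without any 1 array other than scrambled siRNA replicate 1 (adjusted p from 0.0777 to 0.324, the highest without scrambled siRNA replicate 3), with no background correction (0.0526), with the authors' processed values (0.0526), with the other normexp (0.0517), with no filter on dim probes (0.108) or with probes averaged (0.382). Of 31 interferon response genes Dhx58 fell by 0.75 (adjusted p = 0.0428; list adjusted p = 0.136), and 1 rose and 2 fell adjusted over the list alone. The other 2 kept Dhx58 probes did not pass (-0.42 and 0.080), and Dhx58 did not pass without any 1 array other than Gas siRNA replicate 1 (adjusted p from 0.0681 to 0.256, the highest without Gas siRNA replicate 2), with no filter on dim probes (0.0976) or with probes averaged (0.393). Of 14 small RNA silencing genes Ago2 fell by 0.46 (0.0137) and a second kept probe fell by 0.40, while another did not pass (-0.17, adjusted p = 0.827; list adjusted p = 0.215). Ago2, the 1 gene that passed adjusted over the list alone, did not pass without scrambled siRNA replicate 3 (0.0862), Gas siRNA replicate 3 (0.107) or with probes averaged (0.138). The calcium list passed with the stricter filter, with probes averaged and by directional fry, the interferon and small RNA lists with probes averaged, and the unfolded protein list without Gas siRNA replicate 1 (adjusted p = 0.0487).

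Among 8 detected fibroblast, endothelial and immune markers Laptm5 fell by 0.77 (adjusted p = 0.0226; list adjusted p = 0.913), also adjusted over the list alone. Laptm5 did not pass without any 1 array other than Gas siRNA replicate 1 (adjusted p from 0.0730 to 0.108, the highest without Gas siRNA replicate 3) or with no filter on dim probes (0.0670). None of the 46 cell cycle genes (list adjusted p = 0.913), 27 MAPK pathway genes (0.913), 25 apoptosis regulators (0.989) and 24 heat shock and oxidative stress genes (0.224) changed singly in the limma fit of all 6 arrays, and 0 passed adjusted over the list alone. The list of other anterior pituitary lineages had 4 detected members and was not tested, with log2 differences of -0.45 for Gh and -0.080 for Drd2 that did not pass. The list median, mean and test direction differed in sign for lists that were not called, namely the cAMP, cell cycle, apoptosis, MAPK, receptor and fibroblast lists, and median and mean also differed for the untested list of other pituitary lineages.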

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

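The alternatives were listed before the data were examined, except the Gnas knockdown under other filters and averaging, added after. Gnas fell in each of them, with a log2 change of -1.12 with probes averaged and otherwise -2.94 to -2.65 (-2.94 to -2.87 without each array in turn). The count of 196 changed genes (84 higher, 112 lower) fell to 5 (1 and 4) without the intensity trend, where the shared prior has fewer degrees of freedom and 1 SD for all intensities, to 119 (59 and 60) with probes averaged and to 78 (33 and 45) with a 1.5-fold minimum. Leaving out an array gave 104 to 150 genes (43 to 69 higher, 59 to 81 lower) from fewer samples. Background alternatives gave 182 to 184, all among the 196. Scaling could move little, since the deposited values were already normalized. Same-numbered arrays deviated together only weakly. Each scrambled array correlated best with its own number, and 2 of 3 Gas arrays did, a hint from the data and not the design. With the replicate number as a block 290 genes passed (136 higher, 154 lower), all 196 among them, and of the named genes not called Tgfbr1 (-0.30, adjusted p = 0.0439), Sqle (0.0242) and Rplp0 (0.0440) passed. Of 51 called genes named by the fixed rule, 4 besides Gnas kept the call in every alternative run for them, 27 without each array in turn, and 0 changed sign. Against 10 list calls, 6 passed with no filter and 6 without the trend (the cause was not tested), 7 to 8 without each array, 0 with an estimated correlation, 2 by directional fry and 18 by mixed fry. Fry asks another question. Signs turned, all at adjusted p over the threshold, without single arrays for Acvr1b (-0.12 to 0.18), Gnrhr (-0.0086 to 0.073), Lhb (-0.078 to 0.11), Egr1 (-0.059 to 0.14) and Uqcrq (-0.057 to 0.10), and the test direction for the mean of the list of apoptosis regulators (-0.012 to 0.0175; 0.00104 with the block, 0.00275 with array weights), MAPK pathway (-0.030 to 0.00415), cell cycle (-0.016 to 0.021) and fibroblast markers (-0.013 to 0.054; 0.016 without the trend), and receptors (-0.066 without the trend). A slide block does not apply, as the header names 1 chip.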

Other observations

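The genes named in this part and all tests in it except the splits of the arrays were chosen after the values were seen. Outside the fixed lists, 5 genes of lipid metabolism, picked by their values, were lower with Gas siRNA, while of 20 other detected fatty acid synthesis genes 12 had a negative and 8 a positive log2 change, and 0 passed in limma. The fatty acid desaturase genes Fads1, Fads2 and Scd1 had log2 changes of -0.35 (adjusted p = 0.00257), -0.43 (0.0206) and -0.41 (0.0305). Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, fell by 0.86 (adjusted p = 4.85e-06), and Scarb1, a receptor for high-density lipoprotein, fell by 0.65 (0.0158). Fads2 did not pass without scrambled siRNA replicate 1 (0.0948), scrambled siRNA replicate 3 (0.153), Gas siRNA replicate 2 (0.0552), Gas siRNA replicate 3 (0.149) or with probes averaged (0.204). Scd1 did not pass without scrambled siRNA replicate 1 (0.173), scrambled siRNA replicate 3 (0.0846), Gas siRNA replicate 1 (0.122), Gas siRNA replicate 3 (0.145) or with probes averaged (0.0519), and Scarb1 without scrambled siRNA replicate 1 (0.0659), scrambled siRNA replicate 2 (0.0675), Gas siRNA replicate 1 (0.101), Gas siRNA replicate 2 (0.0894) or with probes averaged (0.793). With probes averaged the Scarb1 log2 change was only -0.16. Cyp11a1 did not pass with probes averaged, where its log2 change was only -0.30 (adjusted p = 0.312). Fads1 kept its call without each array.

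The galectin gene Lgals9 and the galectin-binding protein gene Lgals3bp had log2 changes of -0.68 (adjusted p = 1.38e-04) and -0.47 (0.00151). The class I histocompatibility genes H2-D1 and H2-T23 had changes of -0.33 (0.0336) and -0.46 (0.0153). H2-D1 did not pass without scrambled siRNA replicate 2 (0.212), scrambled siRNA replicate 3 (0.120), Gas siRNA replicate 1 (0.234), Gas siRNA replicate 3 (0.0625), with no filter on dim probes (0.0768) or with probes averaged (0.209), and H2-T23 without scrambled siRNA replicate 3 (0.161), Gas siRNA replicate 1 (0.116) or with probes averaged (0.212). In the neighbouring genes of 1 family, Bpifb4 rose by 0.72 (adjusted p = 2.53e-05) while Bpifb3 and Bpifb6 fell, with changes of -0.52 (0.00318) and -0.49 (2.61e-04), and each kept its call without any 1 array.

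The 6 arrays can be split into 3 and 3 in 10 ways. The real split gave 196 changed genes and the highest of the others gave 0, so 1 of 10 splits gave as many, and the smallest share that 10 splits can give is 0.1, too few for a share under 0.05.

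The shift of the ATF4 and amino acid response list was weighed against 1 technical explanation. If an intensity-dependent shift of the arrays had moved it, random lists matched on intensity would move as far. Of 10000 such lists 0 had a median as high as the 0.18 of the list, the highest being 0.13, so the share is given as 1e-04, the smallest that 10000 lists can resolve. Quantile normalization removes such shifts between arrays, however. The outcome was therefore largely fixed in advance and does not decide on that explanation. The 26 members that did not pass had a median of 0.16, but with 27 of the 30 members positive this follows from the list result and decides nothing further. Random lists ignore the correlation between genes, and adjusted p was 0.176 with an estimated correlation, so a response of the cells to Gas siRNA stays a hypothesis and an effect of the siRNA other than through Gnas was not tested.

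The rise of Gdf9 rests on 1 probe, and signal of its neighbour Uqcrq was a candidate source. The Uqcrq log2 change was 0.023, with an upper 95% bound of 0.296, below 0.40, the Gdf9 change divided by 2. This argues against a rise of that size in the signal of the Uqcrq probe. Uqcrq had 1 kept probe, at a mean log2 intensity of 7.80 or the percentile 47.2 of all genes, so the bound covers its transcript only as far as this probe reports it. Other sources of signal on the Gdf9 probe were not tested.

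Inha, Cyp11a1 and Scarb1 are known targets of the nuclear receptor SF-1 or steroidogenic genes, and may have fallen as part of that group. The 6 other detected members of a list of such genes had a median of -0.077, and 11.2% of matched random lists had a lower one, so a small shared fall was not decided. They lay between -0.26 and 0.042, and the lower 95% bound of their mean, from the spread between these genes, was -0.21. That was above -0.36, the upper bound for the brightest Scarb1 probe, so these 6 genes did not on average fall by about the change of that probe. With probes averaged the Scarb1 change was -0.16, and the bound does not speak against a group fall of that size. Lhb, Cga and Gnrhr, 3 of the 6, had been read before, so this outcome was partly known in advance and does not decide on the group. For fatty acid synthesis genes, the 20 other detected members had a median of -0.12, and 0.04% of matched random lists had a lower one, as a small shared fall would give, though 12 of the 20 were negative, 0 passed singly in limma and random lists ignore the correlation between genes. The members of this list and of the SF-1 list were written down after the values of all genes were seen, which limits what these shares can show.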
